A study of Mus musculus with 6 samples.

How the data were processed

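Poly-A RNA sequencing of mouse retina on postnatal day 2 was compared between 3 control samples and 3 samples of Zeb2 loxP/loxP αCre mice, with groups and replicate numbers taken from the sample titles. RNA was extracted with RNeasy mini-kits, per the labels' protocols. The submitters' processing notes name cutadapt, STAR 2.4.2a, HTSeq, DESeq2 and the build GRCm38, without their roles or order. The strand setting of the counting is not given in the sources used here, so overlapping and antisense genes cannot be told apart by strand.

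The deposited values are a normalised count signal per gene and library, rounded by the authors to 1 decimal, in a table of 20175 genes whose file headers name all 6 libraries; 0 other columns of values were present. In each library 100% of the values lay within 0.06 of whole multiples of a single step, the worth of 1 read, so the whole reads could be recovered by dividing by that step (0.846 to 1.06 normalised counts per read). The recovered reads summed to 26041200 to 32614805 per library, which is the depth used here. 488 to 655 genes per library were at 0, and 60 genes were at 0 in every library.

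Because the table holds normalised values, the main test was limma 3.58.1 (R 4.3.3) with a mean-variance trend on log2(normalised count + 1), on the 16064 genes with a mean of at least 10 over the 6 libraries, without covariates. p-values were adjusted by Benjamini-Hochberg and called under 0.05, 2-sided. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. For genes with 3 reads or fewer in a group, the ratio of recovered reads per unit of size factor is given with an exact 95% interval conditional on the total, or, at 0 reads, a lower bound against 3 reads over the group. Zeb2 was also compared by an exact permutation test. Gene IDs were matched to GENCODE M21 (20122 of 20175), which gave coordinates and gene types. 37 rows shared a symbol with another row and were kept apart by their ID.

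The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The rule named Zeb2 and Zeb1; the 12 genes that rose and the 12 that fell with the smallest adjusted p among those whose 3 mutant values all lay above or all below the 3 control values; of each list up to 4 called members, filled to 2 with the most abundant where fewer were called; and the 5 that rose and the 5 that fell with the largest fold change at a mean of at least 50. Some genes taken by this rule are not reported here and were not replaced. There were 34 lists: retinal cell types, pathways, other tissues of the eye, blood and vessel cells, and RNA quality. They held 512 symbols, 13 of which were not analysed here because no row matched them. The 33 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists, with an estimated correlation as an alternative. fry asked whether members moved on balance one way, and called 0 of 33 lists after adjustment, where camera called 14.

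The alternatives were pseudocounts of 0.1 and 5, no filter or a mean of at least 50, 4 other scalings (TMM, median of ratios, quantile, total), array weights, a robust variance, edgeR 4.0.16 on the recovered reads, a replicate block, an Xist covariate, stricter thresholds and leaving out each library. Added after seeing the data were DESeq2 1.42.0 on the recovered reads, a Col1a1 covariate and leaving out mutant libraries 1 and 2.

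The steps were tested on simulated data: reads for the 16064 genes were drawn from the real means and depths, with 200 genes changed. limma called 52.5% of 40 genes raised by 0.5 (log2), 80% of those raised by 1 and 97.5% of those raised by 2, and 40% and 77.5% of those lowered by 0.5 and 1. Of 148 genes called, 9 had not been changed, and 0 genes were called when no gene was changed. Changes of 0.5 on the log2 scale were therefore often missed at this number of samples, and some changes of 1 were missed as well. Smaller changes were not simulated. Each gene was drawn independently of the others, so the simulated error rates leave out variation shared between genes.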

Results

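RNA was sequenced from 6 samples of mouse retina taken on postnatal day 2 (P2), a stage at which progenitors still divide and late-born neurons and glia are being formed. There were 3 control samples and 3 samples with loxP sites in both copies of Zeb2 and the αCre driver, a Cre recombinase active in progenitors of the peripheral retina. The latter are called Zeb2 mutant here. The genotype of the controls and the strain of either group are not given here, so differences between the groups cannot be assigned to Zeb2 alone. Zeb2 encodes a zinc-finger transcription factor that binds Smad proteins, and the title of the series sets the question: how Zeb2 affects interneurons, Müller glia and BMP-Smad signalling. The 3 control libraries held 26064213, 26246179 and 32614805 reads on genes, and the 3 mutant libraries 26041200, 28250928 and 26774660. Libraries of the same group differed by more than sampling noise, with a chi-square per degree of freedom of 8.05 to 14.97. Nothing in the labels says that the samples of a group came from separate animals or litters, so p-values measure only the spread between these samples, which may be technical in part. By their sex-linked transcripts, described below, each group held at least 2 animals.

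Zeb2 itself (ENSMUSG00000026872; GRCm38 chromosome 2, 44983632 to 45117395, minus strand) was lower in every mutant library than in any control library. Its normalised count was 5989.7, 6448.7 and 5916.7 in the controls and 5581.4, 4273.6 and 5049.7 in the mutants, means of 6118 ± 288 and 4968 ± 658 (SD, n = 3 each). The mutant mean was 81.2% of the control mean, a log2 fold change of -0.31 ± 0.090 (SE). This did not pass the test across all genes (limma adjusted p = 0.129, unadjusted p = 0.0079), and the exact 2-sided permutation test of the 6 values gave p = 0.1, the smallest that 3 against 3 samples allow. The call depended on the setting: the adjusted p was 0.0375 without mutant library 1 and 0.0158 with DESeq2, an alternative chosen after seeing the data, and ranged from 0.0158 to 0.316 over all alternatives. The count covers the whole gene, and the sources used here do not say which part is deleted, so transcripts that had lost only that part would still be counted. Cells outside the peripheral retina, where αCre is active, would also add Zeb2 reads, and their share was not measured. The Zeb2 paralog Zeb1 had 2292 ± 70.4 in controls and 2435 ± 27.9 in mutants (limma adjusted p = 0.356).

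Most of the genes that limma called between mutant and control retinas were higher in the mutants. Ptn, which encodes the secreted growth factor pleiotrophin, rose 3.04-fold, from 4084 ± 349 to 12530.1 ± 2201 normalised counts (SD, n = 3 each; limma adjusted p = 0.00174). Gcnt1, a glycosyltransferase gene of O-glycan branching, rose 9.85-fold, from 52.8 ± 18.7 to 511 ± 98.0 (limma adjusted p = 0.00318). Dlk1, a non-canonical Notch ligand, rose 6.74-fold and Dio3, the deiodinase that inactivates thyroid hormone, 6.39-fold (limma adjusted p = 0.00318 and 0.00523). The SoxB1 transcription factor gene Sox1 rose 15.2-fold, with 556.9, 1868.3 and 649 normalised counts in the mutants against 47.4 to 70.3 in the controls (limma adjusted p = 0.00637). Abca8b, Cited4 and Efcab1 rose 5.61-fold, 4.46-fold and 3.68-fold. These 8 genes were called under every alternative run.

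A few of these genes had almost no reads in control retina. Gm44791, annotated as a lincRNA on chromosome 7, had 0 reads in the 3 controls and 432 in the mutants, at least 149-fold higher against a floor of 3 reads over the control group. Calcr, the calcitonin receptor gene, had 2 control and 332 mutant reads, a ratio of 172 with an exact 95% counting interval of 47.3 to 1427. Rfx6, a transcription factor gene known from the pancreas, had 3 and 435 reads, a ratio of 150.4 (51.1 to 732). Mid1-ps1, a pseudogene annotated on chromosome Y with a near-identical parent gene, had 1 and 129 reads (ratio 134, 23.6 to 5324), including a normalised count of 29 in mutant library 2, where the Y-linked gene Eif2s3y stood at 1. Such intervals and floors cover counting error only, and reads of Mid1-ps1 and of the repeated family member Gm3752 (4.57 ± 0.551 against 41.0 ± 7.20, SD, n = 3 each) are uncertain because near-identical copies can share them.

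Genes that fell did so by less. The largest drop among called genes with a mean of at least 50 was that of Lhx1, the LIM-homeodomain gene of horizontal cells, which fell by 1.123 ± 0.165 (SE) on the log2 scale, from 275 ± 15.4 to 128 ± 27.1 normalised counts (SD, n = 3 each; limma adjusted p = 0.0237). Arhgef37 fell by 0.92, Onecut3 by 0.83, Slc27a6 by 0.79 and Bmp3, which encodes a BMP-family ligand, by 0.73. The smallest adjusted p among them belonged to Draxin, a gene of axon guidance, which fell by 0.48 ± 0.062 (limma adjusted p = 0.0156), and to the thyrotropin receptor gene Tshr, which fell by 0.54 ± 0.072 (limma adjusted p = 0.0169). Pmepa1, Phf21b, Mcam, Pole and Mab21l2 fell by 0.34, 0.36, 0.57, 0.40 and 0.39. Tbx2, Heyl and Tfap2c, named again with their groups, were also among the 12 smallest. Without control library 1 no gene fell, and the limma adjusted p of Lhx1, Draxin and Tshr was 0.113, 0.0737 and 0.0945; without control library 2 or 3, 7 or 6 genes fell, and without mutant library 1, 2 or 3, 242, 9 or 8. The limma adjusted p of Draxin and Tshr was 0.0506 and 0.0528 without mutant library 2, that of Tshr 0.0506 and 0.0580 without control library 2 or 3, and that of Lhx1 0.0580 without control library 3. For Arhgef37 and Slc27a6 it was 0.139 and 0.144 without control library 1, 0.101 and 0.0784 without control library 2, 0.0783 and 0.0519 without control library 3, 0.157 and 0.111 without mutant library 2, and 0.112 and 0.0539 without mutant library 3. Arhgef37 lost its call in 10 of 22 alternatives and Slc27a6 in 8. For Pmepa1, Phf21b, Mcam, Pole and Mab21l2 it was 0.103, 0.0945, 0.108, 0.124 and 0.0955 without control library 1, and 0.0642, 0.0699, 0.0811, 0.0828 and 0.0886 without mutant library 2. For Mcam, Pole and Mab21l2 it was 0.0723, 0.0705 and 0.0714 without mutant library 3, for Pole and Mab21l2 0.0722 each without control library 2, and for Pmepa1, Mcam and Mab21l2 0.0580, 0.0580 and 0.0617 without control library 3.

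In total 184 of 16064 genes tested passed an adjusted p of 0.05 with limma, 149 higher and 35 lower, and 2782 had an unadjusted p under 0.05. Of the 184, 69 changed at least 2-fold, 68 of them upwards. In all 184 the 3 mutant values lay on one side of the 3 control values, as they did for 23.2% of all tested genes, where chance gives 10%. Of the called genes 81.0% were higher with limma, but 61.4% with DESeq2, 59.7% without mutant library 1 and 52.1% without mutant libraries 1 and 2. Without any other library the share was 84.5% to 100%. edgeR's quasi-likelihood test on the recovered whole reads called 180 genes, 174 of them in common, and DESeq2 on those reads, chosen after seeing the data, called 868, among them 183 of the 184. The limma count was 27, 108 or 94 without control library 1, 2 or 3, and 600, 58 or 79 without mutant library 1, 2 or 3. Without mutant libraries 1 and 2, a setting chosen after seeing the data, it was 165, of which 70 were among the 184.

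**Figure D1:**
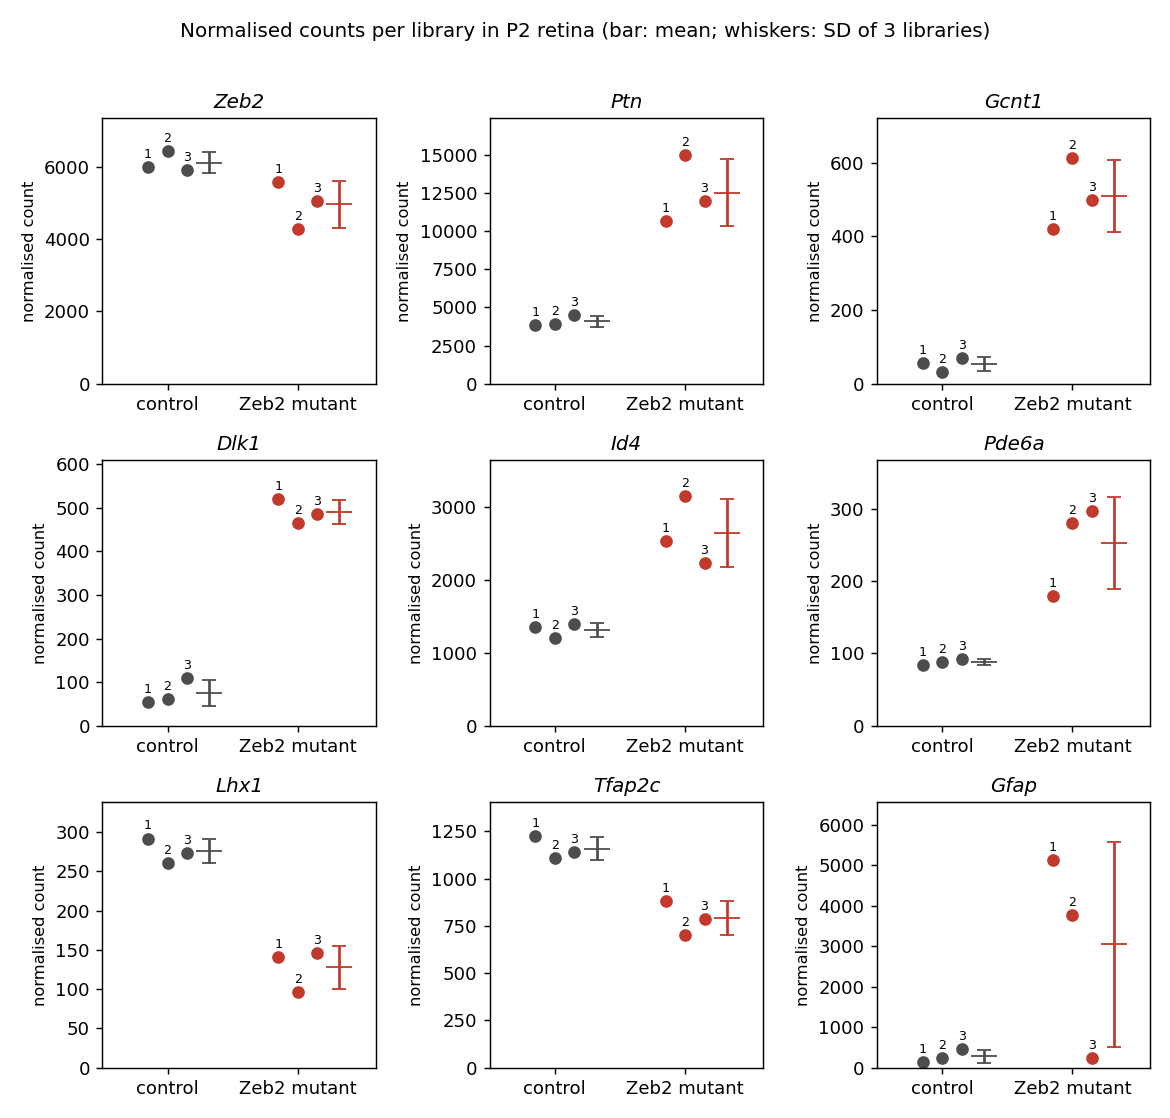
Normalised counts (vertical axis, from 0) of 9 genes in the 3 control (grey) and 3 Zeb2 mutant (red) libraries, with replicate numbers, the mean (bar) and the SD (whiskers). Ptn, Gcnt1, Dlk1, Id4 and Pde6a lie higher and Lhx1 and Tfap2c lower in all 3 mutants, while Gfap is high in mutant libraries 1 and 2 (5130.2 and 3772.4) and not in mutant library 3 (234.6).

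**Figure D2:**
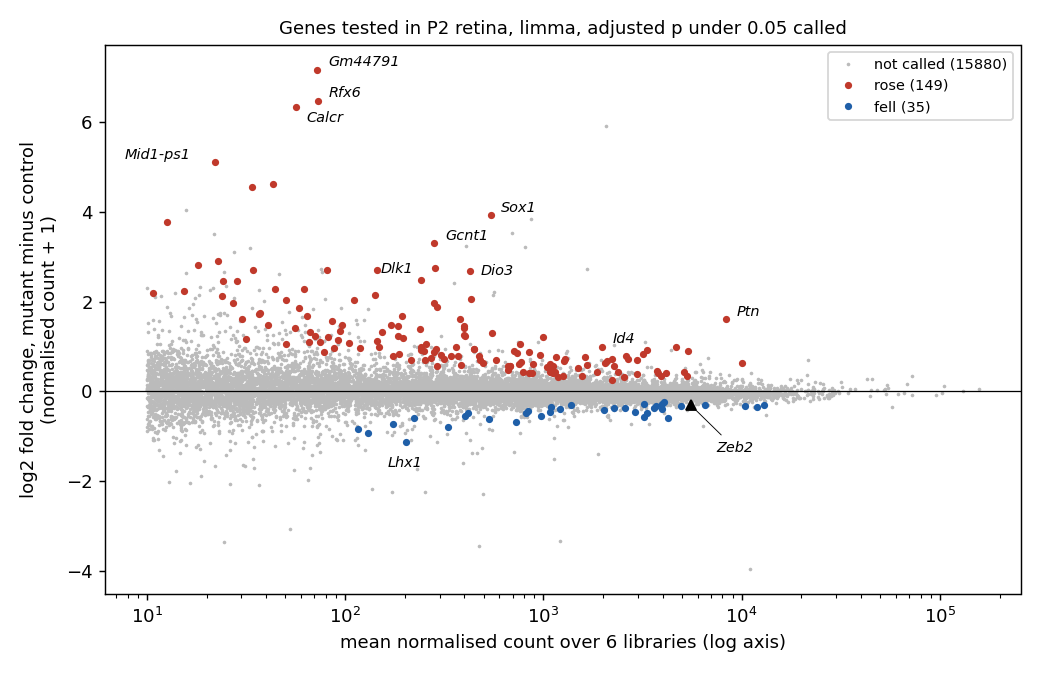
Log2 fold change (mutant minus control, vertical axis) against mean normalised count (log axis) for the 16064 genes tested, with 149 genes that rose in red, 35 that fell in blue and the others in grey. Zeb2 (triangle, -0.31) lies among the genes that were not called.

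Most markers of both inhibitory interneuron types lay lower in mutant retinas. Of 10 horizontal cell genes 7 were lower and 3 higher. Lhx1 and the transcription factor gene Onecut3 fell, the latter from 148 ± 9.03 to 83.2 ± 11.1 (SD, n = 3 each; limma adjusted p = 0.0390). Of 19 amacrine cell genes 16 were lower, and Tfap2c, an AP-2 transcription factor gene of that class, fell by 0.56 ± 0.086 (SE) on the log2 scale (limma adjusted p = 0.0255). Pax6, the amacrine list's most abundant member, had 19527.4 ± 1270.0 against 16880.0 ± 572 (limma adjusted p = 0.127). The median log2 fold change was -0.29 for the amacrine list and -0.26 for the horizontal cell list, and -0.30 for 12 transcription factors that specify these classes. These factors are not a separate set. Tfap2a, Tfap2b, Prdm13 and Barhl2 are also in the amacrine list, and Onecut1 and Onecut2 in the horizontal cell list. None of the 12 was called over all genes, and the most abundant, Neurod1 and Neurod4, had log2 fold changes of 0.043 and -0.13. The limma adjusted p of Lhx1, Onecut3 and Tfap2c was 0.113, 0.161 and 0.134 without control library 1, and 0.0580, 0.0889 and 0.0612 without control library 3. For Onecut3 and Tfap2c it was 0.116 and 0.0697 without mutant library 2, and 0.0705 and 0.0720 without mutant library 3; for Onecut3 it was 0.114 without control library 2.

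Adjusted over the list alone, 12 amacrine genes were lower and 1 higher, 5 horizontal cell genes lower and 1 higher, and 8 of the specification factors lower. The higher amacrine gene was Gad2 (log2 fold change 0.39), which the naming rule did not take and which was not called over all genes. The specification list shares genes with the other lists, so these counts and the tests below are not independent. Camera with a preset correlation of 0.01 placed the amacrine (adjusted p = 1.99e-06), specification (adjusted p = 0.000131) and horizontal cell lists (adjusted p = 0.0150) below the other genes. Each of the 3 calls was lost at adjusted p = 0.472 with an estimated correlation. Mesenchyme and astrocyte transcripts were high in mutant libraries 1 and 2, where the medians of the 3 lists were -0.18, -0.16 and -0.20, and -0.39, -0.44 and -0.47. In mutant library 3, where the mesenchyme and astrocyte medians were lower (-0.72 and 0.15), the medians of the 3 lists were -0.32, -0.24 and -0.25. The astrocyte genes Pax2 and Aldh1l1 still stood above every control in that library, while Gfap and S100b did not. The horizontal cell call was lost without mutant libraries 1 and 2 and on ranks (adjusted p = 0.0801 and 0.106, range over its alternatives 0.00169 to 0.472).

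Photoreceptor genes lay higher. All 17 rod genes had positive fold changes, and Pde6a, Pde6g and Gnat1, which encode parts of the rod phototransduction cascade, rose 2.78-fold, 1.64-fold and 2.27-fold (limma adjusted p = 0.0156, 0.0309 and 0.0476). Pde6a went from 88.1 ± 4.05 to 252 ± 63.4 normalised counts (SD, n = 3 each). All 13 cone genes were higher as well, and Pde6h, the cone phosphodiesterase inhibitory subunit gene, rose 1.87-fold (limma adjusted p = 0.0374), while Gngt2, the most abundant cone gene, had a log2 fold change of 0.022. Of 14 genes shared by rod and cone precursors, Impg1, which encodes a protein of the matrix around photoreceptors, rose 2.398-fold (limma adjusted p = 0.0294), and the more abundant Rbp3 stood at 34519.8 ± 1656 and 35707.4 ± 2944. The limma adjusted p of Pde6a, Pde6g, Gnat1, Pde6h and Impg1 was 0.0926, 0.152, 0.176, 0.0677 and 0.140 without control library 1, and 0.0667, 0.125, 0.170, 0.151 and 0.116 without mutant library 2. It was also above 0.05 for Pde6g, Gnat1, Pde6h and Impg1 without mutant library 3 (0.0882, 0.124, 0.0882 and 0.0882), for Pde6g, Gnat1 and Impg1 without control library 2 (0.0722, 0.1004 and 0.0694), and for Gnat1 and Pde6h without control library 3 (0.0583 and 0.0519).

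The median log2 fold change was 0.53 for the rod list, 0.37 for the cone list and 0.17 for the shared list. Adjusted over the list alone, 13, 9 and 7 genes of these lists were higher and none lower. Camera gave adjusted p = 3.23e-12, 3.41e-07 and 0.00128. With an estimated correlation these became adjusted p = 0.472, 0.472 and 0.605, and the estimated correlation within the rod list was 0.825. The medians of the 3 lists were 0.22, 0.24 and 0.040 in mutant library 1, 0.67, 0.48 and 0.34 in mutant library 2, and 0.72, 0.45 and 0.29 in mutant library 3, where mesenchyme and astrocyte transcripts were lower than in the other 2 mutant libraries. Control library 3 had medians of 0.20, 0.036 and 0.082. Mutant library 1 thus lay close to that control for rod genes and below it for the shared list.

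Müller glia genes moved in both directions. Among 32 members, Ptn and Ndrg2, a gene of glial cells, rose 3.04-fold and 1.59-fold, whereas Sox9, a transcription factor gene of Müller glia and progenitors, fell by 0.28 ± 0.050 (SE) on the log2 scale, and Mfge8, which encodes a secreted phagocytosis ligand, fell by 0.59 ± 0.10 (limma adjusted p = 0.0298 for Ndrg2, 0.0379 for Sox9 and 0.0355 for Mfge8). Without control library 1 the limma adjusted p of Ndrg2, Sox9 and Mfge8 was 0.139, 0.140 and 0.139; without control library 2 it was 0.0652, 0.113 and 0.0864, and without mutant library 3 0.0875, 0.0856 and 0.0580. For Ndrg2 and Sox9 it was 0.125 and 0.130 without mutant library 2, and for Sox9 and Mfge8 0.106 and 0.0748 without control library 3. The list had a median of 0.14, with 8 members higher and 4 lower when adjusted over the list alone. Camera called it higher (adjusted p = 0.00794), a call lost at adjusted p = 0.472 with an estimated correlation. Astrocyte and mesenchyme transcripts were high in mutant libraries 1 and 2, and the call was also lost without those libraries, at a median of 0.015, and with the Col1a1 covariate, at 0.060 (adjusted p = 0.163 and 0.0677, range over its alternatives 7.46e-06 to 0.472). The median was 0.087 without control library 1 and 0.21 without mutant library 3.

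Genes induced by BMP-Smad signalling split as well. Id4, which encodes an inhibitor of bHLH factors, rose 1.99-fold, from 1312 ± 100.1 to 2638 ± 467 (SD, n = 3 each; limma adjusted p = 0.0111), and without control library 1 its adjusted p was 0.0635 (range over its alternatives 7.30e-16 to 0.0635). Id3 had 2242 ± 169 and 2740.5 ± 268 (limma adjusted p = 0.115). Tbx2, a T-box gene of the dorsal retina, fell by 0.31 ± 0.046 (SE) on the log2 scale (limma adjusted p = 0.0237; 0.122, 0.0736 and 0.0580 without control library 1, 2 or 3, and 0.0811 and 0.0545 without mutant library 2 or 3). Of 17 members, 5 were higher and 2 lower when adjusted over the list alone, and 10 had a negative log2 fold change. The 5 were Id4, Id1 (0.38), Id2 (0.41), Id3 (0.29) and Hey1 (0.28), and the 2 were Tbx2 and Smad7 (-0.20). Id1, Id2, Id3 and Id4 each lay higher in every mutant library than in any control library. Id1, Id2, Hey1 and Smad7, which the naming rule did not take, were not called over all genes. The list's median was -0.15 and its mean -0.097, while camera's direction was up, at adjusted p = 0.982. Without control library 2 the list's median was -0.0026. Among 29 ligands, receptors, antagonists and Smads of the BMP and TGF-β pathways, Bmp3 fell and Smad5 stood at a log2 fold change of -0.023. Without control library 1, 2 or 3 the limma adjusted p of Bmp3 was 0.139, 0.0736 or 0.0722, and without mutant library 2 or 3 it was 0.0855 or 0.0669. In that list 4 members were lower when adjusted over the list alone (median -0.043, camera adjusted p = 0.0634). Camera called this list lower in 7 alternatives, on edgeR and DESeq2 fits (adjusted p = 0.0334 and 0.0415), with no filter (0.0409), with the Col1a1 covariate (0.0162) and without mutant library 1 (median -0.11, 0.0345), control library 1 (-0.075, 0.0175) or control library 3 (-0.050, 0.0294). Without control library 2 this list was not called (median -0.043, camera adjusted p = 0.339), the highest adjusted p with any single library left out. The range over its alternatives was 0.0162 to 0.718.

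Cell cycle genes lay slightly lower, with 24 of 26 below 0, a median log2 fold change of -0.14 and no member called, over all genes or over the list alone. The list's medians in mutant libraries 1 to 3 were -0.067, -0.11 and -0.31, and without mutant library 3 its median was -0.080 (camera adjusted p = 0.00270). Ccnd1, the cyclin D1 gene of retinal progenitors, had 63581.1 ± 4066 against 50750.6 ± 8905 normalised counts and Mki67 19749.7 ± 775 against 18136.3 ± 868 (SD, n = 3 each; limma adjusted p = 0.211 and 0.304). Camera called the list lower (adjusted p = 1.99e-06; adjusted p = 0.605 with an estimated correlation), and likewise 15 p53 target and apoptosis genes (median -0.12, adjusted p = 0.00392; adjusted p = 0.472 with an estimated correlation), of which Mdm2 stood at -0.094 and 2 members were lower when adjusted over the list alone. The median of the latter list was -0.19 without control library 3.

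Other lists of the neural retina were not called. Retinal progenitor genes had a median of 0.012, yet their member Fgf3, a fibroblast growth factor gene, rose 3.93-fold, from 108 ± 20.1 to 453 ± 212 (SD, n = 3 each; limma adjusted p = 0.0207). Notch pathway genes had a median of -0.0041, with Heyl, a Notch-induced bHLH gene, falling by 0.34 ± 0.051 (SE) on the log2 scale and Notch1 at -0.0041. Wnt pathway genes had a median of -0.19, with Wnt5a rising 1.64-fold (limma adjusted p = 0.0370) and Dkk3 at 0.20. The Wnt median was 0.036 without control library 2 and -0.10 without mutant library 2, and Dkk3 ranged from 0.080 to 0.26 with single libraries left out. Without control library 1 the limma adjusted p of Fgf3, Heyl and Wnt5a was 0.104, 0.124 and 0.154. For Fgf3 and Wnt5a it was 0.0580 and 0.0872 without control library 3, for Heyl and Wnt5a 0.0811 and 0.130 without mutant library 2 and 0.0583 and 0.0646 without mutant library 3, and for Heyl 0.0722 without control library 2. Camera adjusted p for these 3 lists was 0.798, 0.701 and 0.524. Adjusted over the list alone, 4 progenitor genes were higher and 5 lower, 3 Notch genes higher and 2 lower, and 2 Wnt genes higher and 1 lower.

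Ganglion cell genes (median 0.0089), bipolar cell genes (0.068) and neurogenic progenitor genes (-0.056) had camera adjusted p of 0.360, 0.630 and 0.192. Ganglion cell genes were called higher without mutant library 3 (median 0.071, adjusted p = 0.0130), with medians of -0.027 without mutant library 2 and 0.037 and 0.044 without control library 1 or 2, and neurogenic progenitor genes lower without mutant libraries 1 and 2 and with the Col1a1 covariate (adjusted p = 0.00996 and 0.0191). The neurogenic median was -0.010 without mutant library 3 and -0.011 without control library 2. The bipolar median was 0.023, -0.0018 and 0.12 without mutant library 1, 2 or 3, and 0.0069 and 0.13 without control library 1 or 2. Stmn2 and Gap43 stood at -0.041 and -0.015, Prdm1 at -0.016, and Sox4 and Hes6 at -0.25 and 0.034. Adjusted over the list alone, 3 ganglion cell genes were higher and 1 lower, 1 bipolar gene was lower, and 1 neurogenic gene was higher and 4 lower. Genes of cell cycle exit (-0.15), synapses (-0.0074), axon guidance (-0.091) and the ciliary margin (-0.33) had camera adjusted p of 0.172, 0.630, 0.318 and 0.132. The exit median was -0.033 without mutant library 3, and the axon guidance median -0.019 without mutant library 2 and -0.054 without control library 2. Synaptic medians ranged from -0.059 to 0.031 over the 6 libraries left out. The ciliary margin list stood at a median of 0.49 in control library 2, against -0.22 and -0.30 in control libraries 1 and 3, and without control library 2 its median was -0.066 (adjusted p = 0.877) and without mutant library 3 -0.16 (0.611). It was called lower in 5 alternatives, without control library 1 or 3 (adjusted p = 0.0143 and 0.0114), without mutant library 2 (0.0466), without mutant libraries 1 and 2 (0.0198) and with the Col1a1 covariate (0.00108). The most abundant members of these 4 lists were Btg2 and Cdkn1b (0.079 and 0.036), Map2 and Syt1 (0.084 and 0.050), Ephb2 and Robo2 (-0.13 and -0.21) and Zic2 and Col9a1 (-0.020 and -0.36). Adjusted over the list alone, 1 exit gene was lower, no synaptic gene was called, 3 axon guidance genes were higher and 2 lower, and 2 ciliary margin genes were higher and 1 lower.

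**Figure D3:**
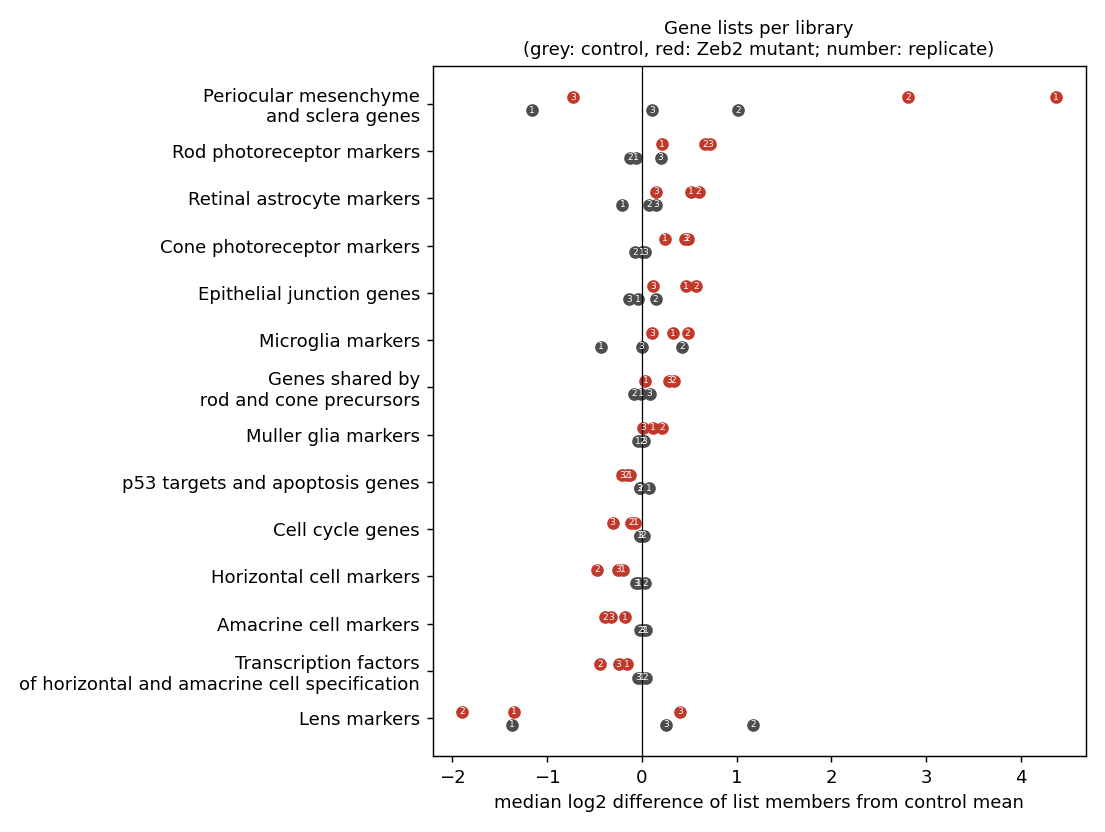
Median log2 difference of each list's members from their control mean (horizontal axis), per control (grey) and Zeb2 mutant (red) library with its replicate number, for the 14 lists called by camera with a preset correlation of 0.01. Rod, cone and interneuron lists shift by under 1 in all mutants, while mesenchyme genes reach 4.37 and 2.81 in mutant libraries 1 and 2 and -0.72 in mutant library 3.

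Transcripts of cells outside the neural retina differed strongly between libraries. Among 9 periocular mesenchyme genes (median 2.15, none called), the collagen gene Col1a2 had normalised counts of 51.1, 203.5 and 95.6 in controls and 2185.2, 779.8 and 58.9 in mutants, and Col5a1 stood at -0.22. Of 8 astrocyte genes (median 0.50), Gfap, the intermediate filament gene of astrocytes and stressed Müller glia, had 143.8, 236 and 466.3 in controls and 5130.2, 3772.4 and 234.6 in mutants. Adjusted over the list alone, 5 astrocyte genes were higher and 1 lower. Lens genes (19 members, median -0.86) stood highest in control library 2, where Cryaa reached 6152.8, against at most 1981.5 elsewhere. All 15 microglia genes were higher (median 0.30), with Csf1r at 460.1 ± 140.3 and 612 ± 10.04 (SD, n = 3 each).

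Camera called mesenchyme (adjusted p = 0.0323), astrocyte (0.0112), lens (0.00439) and microglia genes (0.00593), all 4 lost with an estimated correlation, at adjusted p = 0.761, 0.572, 0.761 and 0.718 with an estimated correlation. Without mutant library 1 the mesenchyme, astrocyte and lens lists were no longer called (adjusted p = 0.435, 0.0656 and 0.0656), without mutant library 2 the mesenchyme, lens and microglia lists (0.116, 0.145 and 0.0905), without control library 1 the mesenchyme and microglia lists (0.187 and 0.171), without control library 2 the lens list (0.272) and without control library 3 the mesenchyme list (0.0570). The mesenchyme median was 0.92, 3.59 and 1.37 without mutant library 1, mutant library 3 or control library 1. The lens median was -0.41 and -1.64 without mutant library 2 or 3 and -1.62 and -0.26 without control library 1 or 2, and the microglia median 0.17 without mutant library 2 and 0.14 and 0.50 without control library 1 or 2. The mesenchyme call was also lost at a mean of at least 50 and with total scaling (adjusted p = 0.104 and 0.0551), the astrocyte and microglia calls with the Col1a1 covariate (0.0828 and 0.337) and without mutant libraries 1 and 2 (0.350 and 0.387). Epithelial junction genes (10 members, median 0.36) were called higher (adjusted p = 0.0148; adjusted p = 0.572 with an estimated correlation; 0.0676 without control library 3; 0.0564 on ranks). Their medians in mutant libraries 1 to 3 were 0.47, 0.58 and 0.12, and without mutant library 3 the list's median was 0.59. Without mutant libraries 1 and 2 the median was 0.12 (adjusted p = 0.190), and with the Col1a1 covariate it was 0.24 (0.0732). Of the junction genes, Epcam rose 3.18-fold, from 90.9 ± 8.98 to 298 ± 84.4, and the keratin gene Krt18 1.73-fold (limma adjusted p = 0.0122 and 0.0499), and 3 were higher when adjusted over the list alone. The limma adjusted p of Epcam was 0.0643 without control library 1, and that of Krt18 0.187 and 0.113 without control library 1 or 3 and 0.0605, 0.170 and 0.0534 without mutant library 1, 2 or 3. Krt18 lost its call in 13 of 22 alternatives, among them edgeR (adjusted p = 0.0549, range over its alternatives 0.000116 to 0.247).

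Pigment epithelium (median 0.20), endothelial (-0.17), pericyte (-0.066) and skeletal muscle genes (-0.079) had camera adjusted p of 0.381, 0.118, 0.968 and 0.326, with no member called. Endothelial genes were called lower without mutant library 1 (median -0.38, adjusted p = 0.0108) or control library 1 (-0.46, 0.000634) and with the Col1a1 covariate (0.0205), while without mutant library 2 or 3 or control library 2 their median was 0.023, -0.28 or -0.0086. Pigment epithelium genes were called higher without mutant library 3 (0.43, 0.00818) or control library 2 (0.30, 0.0180), and their median was 0.029 or 0.0078 without mutant library 1 or 2 and 0.087 or 0.074 without control library 1 or 3. The muscle median was -0.27, -0.14 and -0.0041 without mutant library 1, 2 or 3 and -0.31 and -0.013 without control library 1 or 2. The pericyte median was 0.023 and -0.26 without mutant library 2 or 3 and -0.48, -0.023 and 0.13 without control library 1, 2 or 3. Pmel and Trpm3 stood at 0.23 and -0.15, Kdr and Cldn5 at -0.067 and -0.36, Notch3 and Rgs5 at 0.42 and -0.49, and Mylpf and Myh3 at -0.079 and -0.47. With single libraries left out, Pmel ranged from 0.028 to 0.63, Trpm3 from -0.21 to -0.056, Kdr from -0.12 to -0.029 and Cldn5 from -0.56 to -0.21. Notch3 ranged from 0.29 to 0.50, Rgs5 from -0.79 to -0.14, Mylpf from -0.13 to -0.0041 and Myh3 from -0.62 to -0.36. Immediate early and heat shock genes (0.099, with Jun and Ier2 at -0.037 and -0.057) and mitochondrially encoded genes (0.099, with mt-Co1 and mt-Cytb at 0.048 and 0.11) had camera adjusted p of 0.749 and 0.402, and 1 of the former was higher when adjusted over the list alone. The mitochondrial list was called higher without mutant library 3 (median 0.29, adjusted p = 4.88e-06) and lower without mutant libraries 1 and 2 (-0.30, 0.000156), and its median was 0.034 and -0.034 without mutant library 1 or 2 and 0.048 without control library 1. Mitochondrial transcripts took 1.67% to 2.52% of each library. By Xist and Y-linked genes, control libraries 2 and 3 and mutant library 2 had a female pattern (Xist from 20449.7 to 23565.3) and the other 3 a male pattern (Eif2s3y from 1446.6 to 1901.8), and the sex-linked list had camera adjusted p = 0.470. Fewer than 5 red blood cell genes passed the filter, so that list was not tested.

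Dlk1 and Dio3 lie at the ends of 1 imprinted region of chromosome 12, and its other tested genes were looked up after these values were seen. On GRCm38 with the GENCODE M21 annotation, Dlk1 spans 109452823 to 109463336 and Dio3 110279068 to 110281097, both protein-coding and on the plus strand. Between them lie the non-coding genes Meg3 (109541001 to 109571726), Rian (109603940 to 109661716) and Mirg (109729764 to 109749460). Rian rose by 0.89 ± 0.13 and Mirg by 1.38 ± 0.22 (log2 fold change ± SE, limma adjusted p = 0.0196 and 0.0256). Meg3 had 4364.8, 4688.3 and 5508 normalised counts in controls and 4774.1, 11182.7 and 9964.3 in mutants, and was not called (limma adjusted p = 0.208).

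**Figure D4:**
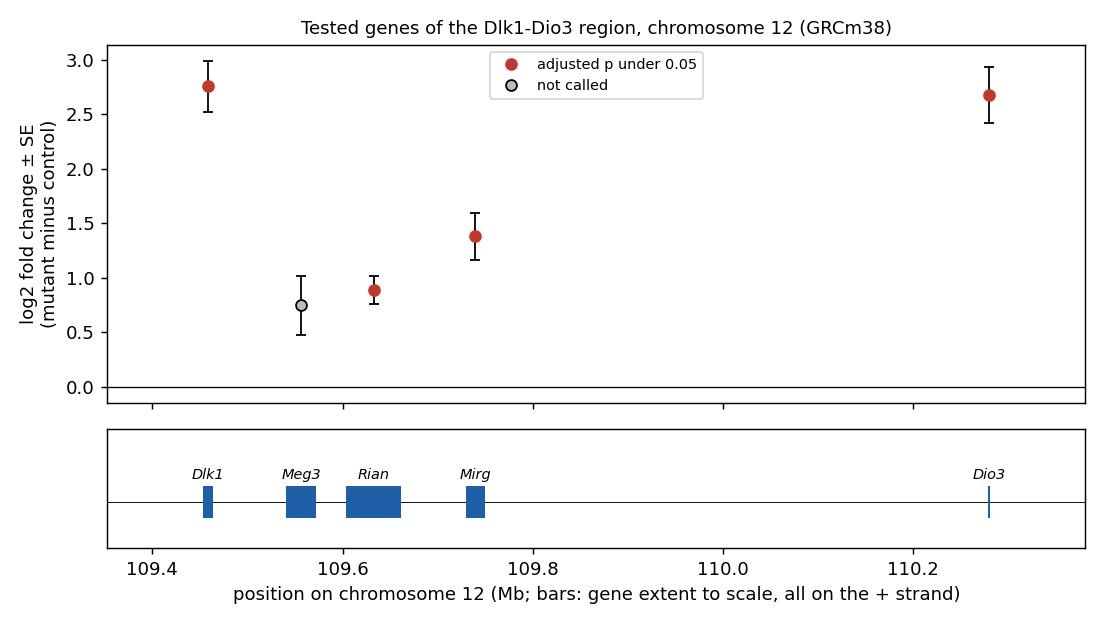
Log2 fold change ± SE (mutant minus control, vertical axis) of the 5 tested genes between Dlk1 and Dio3 on chromosome 12, with the extent of each gene to scale below (GRCm38, Mb). Dlk1 (2.75), Rian (0.89), Mirg (1.38) and Dio3 (2.68) passed the test, and Meg3 (0.75) did not.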

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

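DESeq2 on reads, the Col1a1 covariate and leaving out mutant libraries 1 and 2 were chosen after seeing the data. The table holds no calls by the authors, so the planned count of calls in common with them was not run. Over all alternatives, 1669 values of named genes and 690 of lists kept their direction and side of the threshold, 158 and 38 no longer passed it, 10 and 21 came to pass it, and 51 and 41 changed the sign of the fold change or of the list's test; where a library, gene filter or threshold did not set it by construction, the cause was not tested. None of the 41 called named genes changed sign in any alternative, and 13 were called in every one run for them. That was 21 alternatives for Gm3752 and Mid1-ps1 and 22 for the others. Leaving out libraries gave 27 to 600 called genes, 27 to 358 that rose and 0 to 242 that fell, and a Zeb2 log2 fold change of -0.40 to -0.20.

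Counts of genes changed in Zeb2 mutant retina, genes that rose and genes that fell moved as follows. DESeq2 called 868 genes (533 rose, 335 fell), with Zeb2 at -0.30. At an adjusted p under 0.01, 22 genes were called, 22 higher and 0 lower; with a log2 fold change of at least 0.5, 12 fell. With an estimated correlation, 0 lists were called. The Xist covariate gave 315 genes (225 rose, 90 fell), and 62 fell with robust variance. The Col1a1 covariate gave 109 genes, of which 80 rose. Without mutant libraries 1 and 2, 86 rose and 79 fell.

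A replicate block gave 248 genes, of which 58 fell, and the pericyte list at -0.066 with its test reversed. The numbers share no stated animal or litter, and deviations of same-numbered samples correlated at 0.016, 0.15 and -0.063. Not every sample correlated best with its own number, as control 1 did so with mutant 3 (0.22).

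Signs changed as follows, for values that had not passed the test except those of the lens and mesenchyme lists; of lists the median is given and the sign is that of the test. With TMM factors Notch1 stood at 0.00034 and the BMP target list at -0.15, with array weights Notch1 at 0.0016, and with ranks the BMP target list at -0.15. With total scaling Gap43 was at 9.5e-05, Notch1 at 0.011 and the BMP target list at -0.14. Quantile normalisation gave Prdm1 0.0025, Zic2 0.0064, Gap43 0.0073, mt-Co1 -0.098, Notch1 0.029, Rbp3 -0.032 and the BMP target list -0.15. With the Xist covariate Zic2 was at 0.046, the pericyte list at -0.073 and the sex-linked list at -0.17, and with no filter the muscle list at 0.28. The Col1a1 covariate gave Prdm1 0.068, Smad5 0.0055, mt-Co1 -0.18, mt-Cytb -0.10, Hes6 -0.018, Notch1 0.0097 and Pmel -0.34. With it the BMP target list was at -0.15, ganglion cell -0.055, mesenchyme -0.20, mitochondrial -0.13, progenitor -0.071, pigment epithelium -0.15, stress -0.0016 and synaptic 0.038.

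Without mutant libraries 1 and 2, which leaves 1 mutant library whose spread is assumed to be that of the controls, Gfap was at -0.098, Prdm1 0.13, Smad5 0.012, Kdr 0.0048, Neurod4 0.015, Cryaa 0.046 and Col1a2 -0.75. The same setting gave mt-Co1 -0.37, mt-Cytb -0.25, Hes6 -0.089, Notch1 0.0042 and Pmel -0.57. Its list medians were BMP target -0.14, ganglion cell -0.11, lens 0.41, mesenchyme -0.72, mitochondrial -0.30 (called lower), progenitor -0.10, pigment epithelium -0.20, stress 0.037 and synaptic 0.091. Leaving out single libraries, Prdm1 ranged from -0.088 to 0.021, mt-Co1 from -0.078 to 0.26, Gngt2 from -0.022 to 0.079, mt-Cytb from -0.0075 to 0.29, Hes6 from -0.028 to 0.096 and Jun from -0.096 to 0.013. Zic2 ranged from -0.12 to 0.074, Stmn2 from -0.081 to 0.0071, Gap43 from -0.071 to 0.053, Neurod1 from -0.017 to 0.079, Rbp3 from -0.015 to 0.10, Syt1 from -0.0067 to 0.15 and Notch1 from -0.043 to 0.027. List medians ranged from -0.024 to 0.061 (stress), -0.034 to 0.29 (mitochondrial), -0.48 to 0.13 (pericyte), -0.036 to 0.074 (progenitor), -0.059 to 0.031 (synaptic) and -0.051 to 0.018 (Notch). They ranged from -0.17 to -0.0026 for BMP targets, -0.37 to -0.066 for the ciliary margin and -0.22 to 0.036 for Wnt genes.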

Other observations

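The tests for optic nerve glia, for an equal rise of the other cell types, for imprinted genes in general and for windows of called genes were chosen only after the result was seen, as were the genes and regions named in the next paragraph.

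Next to Id4 on chromosome 13, the transcript A330048O09Rik rose by 2.81, from 3.83 ± 1.55 to 32.5 ± 8.92 (SD, n = 3 each; limma adjusted p = 0.0169). In the first 20 Mb of chromosome 14, 12 of 54 tested genes rose, by 1.42 to 4.54 on the log2 scale. They include predicted genes of near-identical families that can share reads, so their separate values are uncertain, and a strain difference at this locus was not tested. Within 20 Mb of Zeb2 on chromosome 2, 1 of 296 tested genes was called, Ccdc187, which rose by 1.20.

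The 10 splits of the 6 libraries into 3 and 3 cannot give a share under 0.05. The real split called 184 genes and the highest of the others 7, so 1 of the 10 splits gave as many genes. The real split called 14 lists and the highest of the others 17, so 2 of the 10 splits gave as many lists.

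Gfap, Aqp4 and collagen transcripts were high in mutant libraries 1 and 2. Mutant library 3 lacked the pattern (Gfap at 234.6), which already spoke against reactive Müller glia in every mutant retina. Over all mutants, 12 reactive glia genes other than Gfap had a median log2 fold change of 0.0501 with an upper quartile of 0.16. Reactive glia in mutant libraries 1 and 2 alone were not tested. Connective tissue in those 2 libraries may account for the pattern: 16 fibroblast genes stood at a median of 0.849 above the other 4 libraries (quartiles 0.31 to 1.83), between the bounds set for either outcome. Optic nerve astrocytes could too, with a median of 0.605 over 14 optic nerve glia genes, which left this open as well. The other 4 libraries included control library 2, where the mesenchyme list had a median of 1.02, against -1.16 and 0.11 in control libraries 1 and 3. The fibroblast comparison may therefore understate the difference from the remaining libraries. Between the groups, Gfap and Col1a2 were not called (limma adjusted p = 0.219 and 0.357). Camera's calls of the mesenchyme and astrocyte lists were lost with an estimated correlation. Since mutant library 3 lacked the pattern, a difference by genotype could not be told apart from a difference between libraries.

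Rod and cone genes were higher and interneuron genes lower in mutant retinas. A loss of interneurons that raised the share of every other cell type alike was tested. Rod and cone genes lay 0.449 (log2) above ganglion cell, progenitor and bipolar genes (95% bootstrap interval 0.257 to 0.601). That interval resampled genes, not libraries, so it does not measure the spread between samples. Rod medians were 0.22, 0.67 and 0.72 and cone medians 0.24, 0.48 and 0.45 in mutant libraries 1 to 3. Those of ganglion cell genes were 0.084, 0.096 and -0.11, of progenitor genes 0.0046, 0.16 and -0.10, and of bipolar genes -0.022, 0.21 and 0.0035. These medians argue against an equal rise, although the rod median was 0.20 in control library 3. Mutant retinas further on in development could not be told apart from a change by genotype. With the cell cycle median as a covariate the rod median went from 0.53 to 0.26, 48.6% of its size, the amacrine median from -0.29 to -0.20, the cone median from 0.37 to 0.30 and the interneuron specification median from -0.30 to -0.23, and camera with the preset correlation still called all 4 lists (adjusted p = 5.23e-05, 1.85e-05, 5.23e-05 and 0.000343). Without the covariate these 4 calls were lost with an estimated correlation (adjusted p = 0.472 each).

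Dlk1, Rian, Mirg and Dio3 on chromosome 12 were higher in mutant retinas. Connective tissue RNA was argued against, since with a Col1a1 covariate the median of the 5 tested genes was 1.58, against 1.38 without it, and 4 were still called. A chance run gave 2 answers: a 1 Mb window with as many called genes came up in 22.28% of 10000 random draws, but one as dense in called genes in 0.07%, a test added once the first had been seen. The draws placed called genes independently of one another, so they cannot say why neighbouring genes changed together. A 1 Mb window on chromosome 14 held 5 called genes of 7 tested, against 4 of 6 here. Imprinted genes in general stayed open, with 24.4% of 45 outside the chromosome 12 region at an unadjusted p under 0.05 (95% interval 12.9% to 39.5%) against 17.3% of all genes. Those 11 were 6 higher and 5 lower, and the 45 had a median of -0.0054. Of the 45, 2 were called over all genes and both were higher, Calcr by 6.32 and Zdbf2 by 0.56 (limma adjusted p = 0.00174 and 0.00676). A shared change of the imprinted region on chromosome 12 may be involved, a hypothesis found and tested on the same 6 libraries. Meg3 did not rise in every mutant, since at 4774.1 in mutant library 1 it lay within the control range of 4364.8 to 5508.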
